A study of Homo sapiens with 96 samples.

How the data were processed

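Cancer-associated stroma (61 samples) and tumor epithelium (35 samples) were cut from frozen sections by laser microdissection, and their RNA was amplified with Affymetrix's 2-cycle protocol, labelled with biotin and hybridised to U133 Plus 2.0 arrays, per the labels' protocols. The submitters' processing notes name RMA, a method that corrects background, normalizes arrays and summarizes probes, with no version. The values are log2 expression as deposited by the authors. The notes used here do not describe any centring, but the values show it. For 100% of 54675 probe sets the median over the stroma arrays is 0 within 1e-06. Over the tumor arrays it is 0 for 33.2% of the 39307 probe sets with values, with 1st and 99th percentiles of -0.104 and 0.187, so the step used for those arrays is unsettled. Array medians lie between -0.0831 and 0.199 in stroma and between -0.0941 and 0.194 in tumor epithelium. The tumor columns are blank for 15368 probe sets, 15312 of them in an unbroken run of rows, and usual probe sets of some marker genes fall there. To check that rows stay aligned around that run, 588 pairs of probe sets of the same gene on either side were compared over the tumor arrays, with a median r of 0.512 against 0.0841 for random pairs.

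The tests fixed before the data were examined assumed uncentred values. A test of levels between stroma and tumor epithelium with limma, its gene set tests and the count of ligands and receptors on opposite sides were void, because centring fixes their outcome, and were not run. The correlations between compartments used the planned tests, but with another choice of probe set per gene and another filter, as given below. The comparisons of spread, the coordination of lists among stroma samples and the correlations with epithelial and fibroblast scores were chosen after the values were seen, as replacements.

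Samples were paired by the number in their titles, shared by 34 samples of each compartment; the labels do not state that the number marks a patient. The 27 unpaired stroma samples entered the stroma analyses, and the unpaired tumor sample the tumor analyses. No labels give a scan date, batch or array position. The highest correlation between any 2 arrays over genes was 0.957, and no arrays were merged.

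Probe sets were named through GEO's platform annotation. Of all probe sets, 41097 name a single gene, 1801 several and 11777 none; 41043 matched a current gene by Entrez number and 0 symbols changed. The 59 probe sets of XIST, TSIX and Y-linked genes were left out. For each gene the probe set with the largest SD was used (the mean of both compartments' SDs where both enter), because the planned choice by level is impossible after centring, which leaves 19740 genes in stroma and 15191 in both. A dim probe set can then stand for a gene whose main probe set is blank in the tumor columns: DCN has an SD of 2.75 in stroma with its main probe set and 0.588 with the shared one.

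The 46 gene lists, 16 of them cell type markers, and 158 ligand-receptor pairs were fixed before the data were examined. A list score is the mean of its members' values, each centred within its compartment; lists with fewer than 3 measured members were not tested, which left out 3 lists between compartments. Correlations are Pearson's r and Spearman's rho with two-sided permutation p from 100000 resamples, Benjamini-Hochberg adjustment over the lists or pairs of a family, and r without the 2 samples farthest from the median on the stroma, epithelial or fibroblast side. For all genes at once the pairing was permuted 1000 times. Spread was compared per gene with the two-sided Pitman-Morgan test for paired variances, calling an adjusted p under 0.05 and an SD ratio of at least 2, and per list by swapping the compartments within pairs 100000 times. Coordination is the mean correlation between members, set against 10000 random lists matched on SD, one-sided. Members of a list that overlap a marker score were removed before it was correlated with that score. The first axis is the first principal component of the genes in a compartment.

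Named genes followed the fixed rule where it could be applied, which is the 12 genes with the highest correlation between compartments. Its other parts rest on level differences, so the 12 largest SD ratios per side and examples within lists were chosen after the values were seen. On simulated data with 15191 genes, the correlation count recovered 98.5% of 200 genes with a true r of 0.7, and 45.5% when each compartment carried an axis of its own. In the latter case the r of 0.7 held before the axes were added, which dilute it. Unplanted genes over the threshold numbered 17 and 8. The spread test recovered 49.5% of 400 genes with a 2-fold SD ratio and 98.75% with a 3-fold ratio, calling 1 and 4 unchanged genes. Apart from the planted correlations and the added axes, these values were drawn as normal and independent between genes and compartments. The few false calls therefore do not cover linked genes or samples far from the rest, and swaps of the real data called more, as given below. Without an effect, 4.5% of simulated list correlations and 4.9% of list spread tests had p under 0.05.

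The settings varied as fixed beforehand were centring each array on its median, removing the first principal component, regressing out the ratio of 3-prime to 5-prime control probe sets (on stroma arrays alone, since the control rows are blank in tumor epithelium) and Spearman in place of Pearson correlation for ligand-receptor pairs. A filter on SD replaced the planned filter on level. Other ways to combine probe sets, tests without the pairing and leaving out each pair were added after the values were seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.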

Results

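Gene expression was measured in laser-microdissected tissue from primary high grade serous ovarian cancers of untreated patients, in 61 samples of cancer-associated stroma and 35 samples of tumor epithelium, with 1 array per sample. For 34 stroma samples and 34 tumor epithelium samples the labels carry a shared number, and these were treated as 34 pairs, although the labels do not state that the number marks a patient. The series names signaling between the fibroblasts and the cancer cells as its question. The deposited log2 values have a median of 0 over the stroma samples for each probe set and medians near 0 over the tumor epithelium samples, where the centring step is not known, so a higher or lower level in stroma than in tumor epithelium cannot be read from them. The comparisons below therefore concern how genes varied among stroma samples, how far a gene or gene group varied together in both compartments of a pair, and in which compartment it varied more. The number of arrays limits the precision of every value.

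Genes of recognisable cell types and responses rose and fell together among the 61 stroma samples. Immediate early genes, the rapid transcriptional response to stimulation, were the most tightly linked of the 46 fixed lists, with a mean correlation of 0.66 between their 12 measured members once the first axis of variation had been removed. Epithelial markers, with 18 members, came next at 0.5534, followed by endothelial markers at 0.5525 over 13, interferon-stimulated genes at 0.54 over 17 and mucins and kallikreins at 0.53 over 10. Macrophage markers reached 0.53 over 11, antigen presentation genes of MHC class I 0.51 over 11 and mitotic cell cycle genes 0.51 over 18. Among the lists under 0.5, B and plasma cell markers reached 0.43, smooth muscle and myofibroblast markers 0.41, and T and NK cell markers 0.35. With that axis removed, the most variable members were FOSB (SD 1.90 log2 units) and JUN (1.89) among immediate early genes, IFIT3 (1.58) and RSAD2 (1.45) among interferon-stimulated genes, and the immunoglobulin heavy chain IGHM (2.48) and the J chain JCHAIN (2.02) among plasma cell genes. In the same setting the largest spread of single genes belonged to the immunoglobulin light chain IGLC1 (SD 2.84), the proteoglycan EPYC (2.68), the complement component C7 (2.62), the WNT antagonist SFRP2 (2.62) and the collagen chain COL1A1 (2.58). As deposited these 5 genes had SDs of 3.29, 3.177, 2.64, 3.17 and 3.11, in another order. IGLC1 has near-identical copies, so its probe set can read more than a single gene. In all, 37 of the 46 lists had a higher mean correlation than random lists matched on spread at adjusted p under 0.05 (10000 random lists, Benjamini-Hochberg), and each list named so far had p = 1e-04, the smallest the draws can give, and an adjusted p of 0.00024. The lists that missed it were those of the TGF-beta, BMP, WNT and Hedgehog pathways, FGF and ERBB ligands and receptors, integrins, and neutrophil and Schwann cell markers. With the values as deposited, 13 lists passed. Immediate early genes (adjusted p = 0.060), B and plasma cell markers (adjusted p = 0.209) and smooth muscle and myofibroblast markers (mean correlation 0.383 against 0.420 for random lists, adjusted p = 0.671) were not among them.

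**Figure D1:**
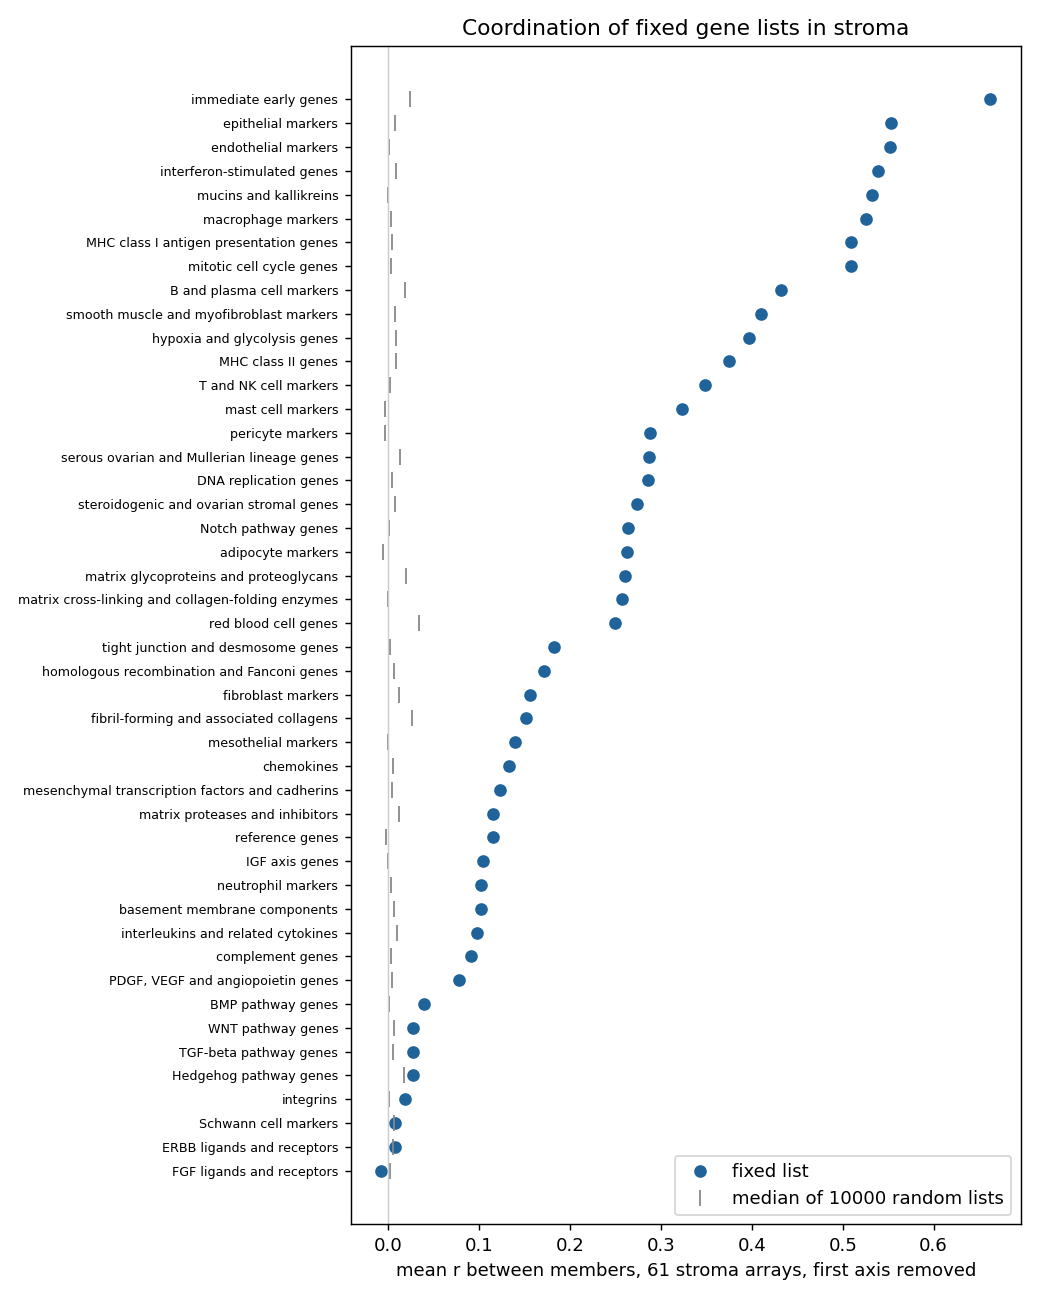
Each dot is the mean Pearson correlation between the measured members of a fixed gene list across 61 stroma samples after removal of the first axis of variation, and each grey bar is the median of 10000 random lists of the same size and spread. Immediate early genes sit highest at 0.66, and FGF ligands and receptors lowest.

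Over the 19740 genes measured in stroma, the first axis carried 53.6% of the variance among stroma samples and the second 8.16%. Matrix genes followed the first axis closely. The score of fibril-forming collagens had r = -0.945 with it (rho = -0.946, and r = -0.937 without the 2 farthest samples), and 18 of 46 lists had r under -0.8. The reference genes, which every cell uses, had r = -0.971 (rho = -0.968, and r = -0.974 without the 2 farthest samples). The axis was computed from the same values, so a permutation p cannot test these correlations and none is given. Its sign was set so that the reference genes fall, so only a shared or opposite side can be read. Schwann cell markers, with 3 members, lay on the side opposite to the reference genes (r = 0.757, rho = 0.787). With the axis removed their mean correlation fell from 0.357 to 0.0082, against 0.0072 for random lists. The bacterial control TrpnX-M lay on that side too (r = 0.801), so this is not shown to reflect Schwann cells. Over the 15191 genes measured in both compartments, the first axis carried 47.6% of the variance in stroma and 35.01% in tumor epithelium. Across the 34 pairs these 2 axes had r = 0.102 (permutation p = 0.566).

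Markers of epithelial cells varied among the stroma samples, with EPCAM (SD 1.93 with the axis removed) and the vesicle protein MAL2 (1.83) the most variable of 18. Genes of the tumor lineage moved with them. The score of mucins and kallikreins had r = 0.894 with the epithelial score (rho = 0.731, permutation p = 1e-05, adjusted p = 4.5e-05, and r = 0.866 without the 2 farthest samples), and that of serous and Mullerian lineage genes had r = 0.878. The reference genes moved with the epithelial score too, with r = 0.675 (rho = 0.688, adjusted p = 4.5e-05) and r = 0.561 with the first axis removed (adjusted p = 9e-05), as did hypoxia and glycolysis genes, with r = 0.720 and 0.537. With the values as deposited 34 of 45 lists correlated positively with the epithelial score and 2 negatively, at adjusted p under 0.05. With the first axis removed these counts were 9 and 6, and the direction turned for fibroblast markers, from r = 0.445 (adjusted p = 0.00047) to -0.371 (adjusted p = 0.012), and for mesenchymal transcription factors and cadherins, from 0.313 (adjusted p = 0.019) to -0.680 (adjusted p = 9e-05). Mucins and kallikreins kept theirs, at r = 0.925.

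Among the 35 tumor epithelium samples, several matrix and mesenchymal lists moved with the score of 6 fibroblast markers. The score of matrix glycoproteins and proteoglycans had r = 0.828 with it (rho = 0.796, permutation p = 1e-05, adjusted p = 0.000105, and r = 0.767 without the 2 farthest samples), that of fibril-forming collagens had r = 0.821, and that of mesenchymal transcription factors and cadherins had r = 0.751. Mesothelial markers, with 3 members, also passed (r = 0.463, adjusted p = 0.030; rho = 0.609, adjusted p = 0.0012). Markers of smooth muscle (r = 0.220, adjusted p = 0.425), pericytes (r = 0.308, adjusted p = 0.229), endothelium (r = 0.102, adjusted p = 0.740) and macrophages (r = 0.229, adjusted p = 0.413) did not pass, nor did basement membrane components (r = 0.351, adjusted p = 0.145) and matrix cross-linking enzymes (r = 0.0552, adjusted p = 0.877). By Spearman's rho with the first axis removed, smooth muscle (rho = 0.489, adjusted p = 0.018), pericyte (rho = 0.496, adjusted p = 0.017) and T and NK cell markers (rho = 0.420, adjusted p = 0.045) did pass. Of the fixed markers, 4 of 7 for pericytes and 4 of 12 for macrophages were measured in both compartments. Across the paired tumor epithelium samples VWF (SD 0.201), TIE1 (0.160), MYH11 (0.201) and ACTA2 (0.264) varied little. EMCN (0.830), SYNPO2 (1.075), RGS5 (1.24) and MS4A7 (1.21) varied more. A score whose members vary little may miss the threshold, so the Pearson misses do not show that RNA of these cell types was absent. In total, 9 of 42 lists correlated positively with the fibroblast score and 0 negatively at adjusted p under 0.05. The count with the first axis removed was 8 positive.

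Whether both compartments of a pair vary together was asked first for each gene. Of 15191 genes measured in both, 261 had a Pearson correlation over 0.5 across the 34 pairs, and 3 had one under -0.5. With the pairing permuted 1000 times the median count was 20, the 95th percentile was 81.05 and the highest was 465; 5 draws gave as many (p = 0.0060). With the first axis of each compartment removed, 401 genes exceeded 0.5, against a highest permuted count of 97 (p = 0.0010, the smallest the draws can give), and 171 genes did so in both settings. The median correlation of all genes was 0.119, just above the central range of the permuted pairings, -0.108 to 0.110. The 12 genes with the highest correlation were SNHG27, PRAMEF12, GCNA, ADGRG7, PROK2, LINC02899, ANKRD12, SIX3, SIMC1P1, IGLC1, COX8C and TAF3, with r from 0.739 to 0.933. For 10 of them r fell under 0.5 without the 2 pairs farthest from the stroma median. TAF3, IGLC1 and SIMC1P1 were among these, with r = 0.387, 0.279 and 0.303 without those pairs, but had rho = 0.434 (p = 0.010), 0.460 (p = 0.0060) and 0.417 (p = 0.015). SNHG27 had r = 0.933 (permutation p = 0.00036) but rho = 0.250 (p = 0.154) and r = 0.0658 without those pairs. The other 2 genes kept r of at least 0.5. ANKRD12, which encodes a protein with ankyrin repeats, had r = 0.771 (permutation p = 2e-05), rho = 0.574 (p = 0.00043) and r = 0.607 without those pairs, and the long non-coding RNA LINC02899 had r = 0.780 (p = 0.00025), rho = 0.602 (p = 0.00032) and r = 0.600. These p-values are not adjusted for the choice from 15191 genes. The highest r of a permuted pairing had a 95th percentile of 0.8265, which SNHG27 and PRAMEF12 alone exceeded. By Spearman's rho, 132 genes passed 0.5, against a median count of 14 and a highest count of 321 in 100 permuted pairings.

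**Figure D2:**
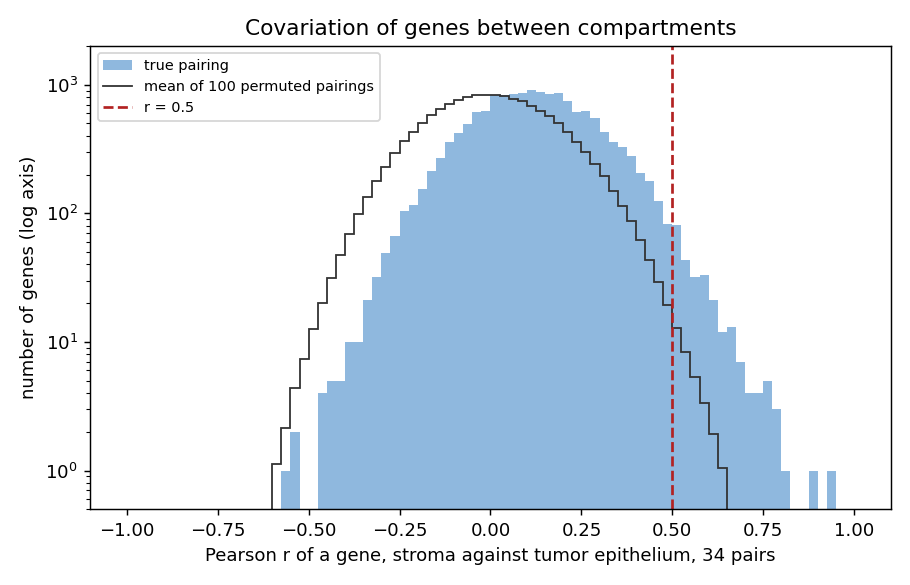
The filled histogram shows the Pearson correlation of each of 15191 genes between stroma and tumor epithelium across 34 pairs, and the line shows the mean of 100 permuted pairings; the vertical axis is logarithmic. The true pairing lies to the right, with 261 genes past the dashed line at 0.5.

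Among fixed gene groups, 4 of 43 lists with at least 3 members measured in both compartments varied together at adjusted p under 0.05 by Pearson correlation. Matrix glycoproteins and proteoglycans had r = 0.538 (permutation p = 0.0010, adjusted p = 0.029) and rho = 0.4998 (p = 0.0032, adjusted p = 0.062), with 12 members. Mitotic cell cycle genes had r = 0.529 (p = 0.0014, adjusted p = 0.029) and rho = 0.467 (p = 0.0058, adjusted p = 0.062), with 9 members. Matrix proteases and their inhibitors had r = 0.505 (p = 0.0020, adjusted p = 0.029) and rho = 0.557 (p = 0.00093, adjusted p = 0.040), with 10 members. Interferon-stimulated genes had r = 0.491 (p = 0.0035, adjusted p = 0.038) and rho = 0.472 (p = 0.0056, adjusted p = 0.062), with 8 members. Across all 35 tumor epithelium samples the scores of matrix glycoproteins (r = 0.828) and matrix proteases (r = 0.691, adjusted p = 0.000105) followed the fibroblast score. Across all 61 stroma samples, with 18 and 17 members, those of mitotic genes (r = 0.620, adjusted p = 7.5e-05) and interferon-stimulated genes (r = 0.540, adjusted p = 7.5e-05) followed the epithelial score. With the first axis removed these had r = 0.449 (adjusted p = 0.0014) and 0.181 (adjusted p = 0.297). In the 34 paired stroma samples, with 8 members, the interferon score had r = 0.346 with the epithelial score. Without the 2 pairs farthest in stroma the 4 correlations between compartments were 0.519, 0.459, 0.441 and 0.441, and both scores lay on the same side of their means in 24, 23, 21 and 22 of the 34 pairs. The small proteoglycan OGN (r = 0.56, but 0.20 without the 2 farthest pairs) and fibrillin FBN1 (0.49) led the matrix glycoproteins, the spindle protein NUSAP1 (0.48) and the mitotic kinesin KIF20A (0.46) the mitotic genes, the metalloprotease ADAM12 (0.48) the proteases, and XAF1 (0.59) and IFIT3 (0.54, but 0.37 without those pairs) the interferon-stimulated genes. Of the members, 1 of the matrix glycoproteins, 2 of the interferon-stimulated genes and 0 of the other 2 lists exceeded 0.5. With the first axis of each compartment removed, interferon-stimulated genes alone passed (r = 0.554, p = 0.00074, adjusted p = 0.032), and the others had r = 0.252, 0.409 and 0.269 with adjusted p = 0.371, 0.189 and 0.371. Leaving out each pair in turn gave r between 0.448 and 0.534 for interferon-stimulated genes, and the adjusted p stayed under 0.05 in 20 of 34 cases, as it did in 32 for matrix glycoproteins, 32 for mitotic genes and 27 for matrix proteases. The number of lists that passed ranged from 0 to 6 over these cases.

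**Figure D3:**
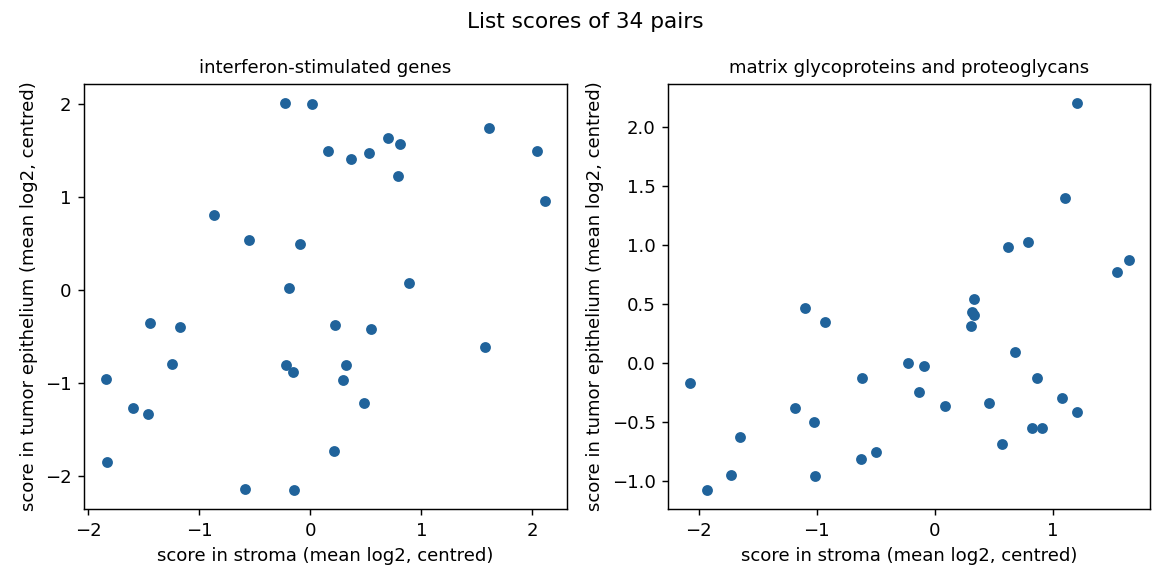
Each dot is a pair of samples, with the mean centred log2 value of the list in stroma on the horizontal axis and in tumor epithelium on the vertical axis, for interferon-stimulated genes (8 members, r = 0.491) and matrix glycoproteins and proteoglycans (12 members, r = 0.538). Higher scores in stroma go with higher scores in tumor epithelium, with a wide scatter.

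Signaling from stroma to tumor was addressed by setting the ligand in stroma against its receptor in tumor epithelium. Of the 158 fixed pairs 81 were measured, and none of these passed adjusted p under 0.05, by Pearson or Spearman permutation test. The other fixed pairs could not be tested. At unadjusted p under 0.05 there were 6 pairs by Pearson and 8 by Spearman. The lowest Pearson p belonged to the death ligand TNFSF10 with its receptor TNFRSF10B (r = 0.471, p = 0.0054, adjusted p = 0.437; rho = 0.438, p = 0.010, adjusted p = 0.396), and r was 0.321 without the 2 farthest pairs. This pair and those that follow are named although they missed the threshold, and were chosen after their values were seen. ARTN with GFRA3 had r = 0.416 (adjusted p = 0.486), and DLL4 with NOTCH1, a ligand and receptor of the Notch pathway, had r = -0.392 (adjusted p = 0.486) and r = -0.0325 with the first axis removed. DLL1 with the same receptor had the opposite sign, r = 0.380 (p = 0.030, adjusted p = 0.486), and r = 0.227 with the first axis removed. The lowest Spearman p belonged to WNT2B with FZD4 (rho = 0.441, p = 0.00998, adjusted p = 0.396). That pair had r = 0.379 (adjusted p = 0.486), and r = 0.153 with the first axis removed.

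Genes that varied more in tumor epithelium outnumbered those that varied more in stroma. In the paired test 1691 genes had at least a 2-fold larger SD in tumor epithelium and 698 in stroma, at adjusted p under 0.05 (Pitman-Morgan test, Benjamini-Hochberg over 15191 genes). With compartments swapped at random within pairs, the same test called a median of 118 genes on the larger side, and at most 405. The largest ratios on the tumor side belonged to TRHDE, a peptidase that cleaves thyrotropin-releasing hormone (SD 1.06 in tumor epithelium against 0.104 in stroma), the protocadherin PCDHB3 (1.496 against 0.148), TRDV3, ABCA13, DCAF12L1, CDC20B, C7orf57, PTGR2, the developmental transcription factors ZIC2 (1.57 against 0.199) and SP8 (1.77 against 0.227), NUS1P3 and FAM201A. On the stroma side they belonged to ZPLD1 (1.14 in stroma against 0.141), ADAMTSL1, an extracellular matrix protein of the ADAMTS family (1.38 against 0.208), the growth factor FGF1 (0.735 against 0.139), GNG8, LOC100505915, TMEFF2 (2.17 against 0.468), SERP2, LINC02624, the protease ADAMTS16 (0.855 against 0.196), FCRL4, the corneal proteoglycan KERA (1.21 against 0.285) and RIDA. With the first axis removed the counts were 1508 and 513, of which 1266 and 312 genes were called in both settings. The median log2 SD ratio of stroma over tumor epithelium of all genes was -0.083, and -0.101 with the first axis removed. A gene near background varies little, so a difference in spread may be a difference in level, which the centring hides. It may also come from a difference in processing or array quality between compartments, which was not tested.

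Of 12 collagens 3 varied more in stroma and 0 in tumor epithelium, with COL1A1 (SD 3.29 in stroma against 1.15) and COL5A3 (1.13 against 0.423). With the first axis removed these 2 kept log2 SD ratios of stroma over tumor epithelium of 1.83 and 1.64. The third, COL8A2, fell from 1.02 to 0.20 (Pitman-Morgan adjusted p = 0.575). The ratio of the whole collagen score turned from 0.46 to -0.61, past adjusted p under 0.05 in neither setting. ITGA11, a collagen-binding integrin, had 1.42 against 0.426, EGFR 2.35 against 0.988, and the chemokine CXCL14 2.65 against 0.942. On the tumor side were MUC4 (1.75 in tumor epithelium against 0.516) and KLK5 (1.40 against 0.548) 2 of 6 mucins and kallikreins, the junction protein TJP3 (0.960 against 0.270), 1 of 2 called among 12 tight junction and desmosome genes, the EGFR ligand BTC (1.84 against 0.320), the chemokine CCL28 (1.13 against 0.250) and FGF9 (1.24 against 0.349). Counts adjusted over the list alone were the same as those over all genes for each of the 43 lists. As whole scores, homologous recombination and Fanconi genes varied more in tumor epithelium (SD 0.581 against 0.232, within-pair permutation p = 0.00021, adjusted p = 0.0045), with 3 of 4 measured members called, BRIP1, FANCI and BARD1. Integrins (0.501 in stroma against 0.260, adjusted p = 0.0045), PDGF, VEGF and angiopoietin genes (0.359 against 0.203, adjusted p = 0.021) and MHC class I genes (1.24 against 0.782, adjusted p = 0.021) varied more in stroma. Of their members 2 of 11 integrins passed in stroma and 1, ITGA9, in tumor epithelium, against 0 of 12 PDGF, VEGF and angiopoietin genes and 0 of 7 MHC class I genes. With all probe sets of a gene averaged, 0 lists had a larger spread in stroma. With the first axis removed these 3 had log2 SD ratios of -0.42, -0.37 and -0.04 and adjusted p of 0.124, 0.318 and 0.952, while the recombination genes had -1.19 (adjusted p = 0.013). In that setting interferon-stimulated genes also varied more in tumor epithelium (-0.64, adjusted p = 0.013), and B and plasma cell markers (1.33, adjusted p = 0.013), red blood cell genes (0.92, adjusted p = 0.040) and reference genes (0.66, adjusted p = 0.036) more in stroma. With the values as deposited, the 39 other lists did not pass in the paired test.

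**Figure D4:**
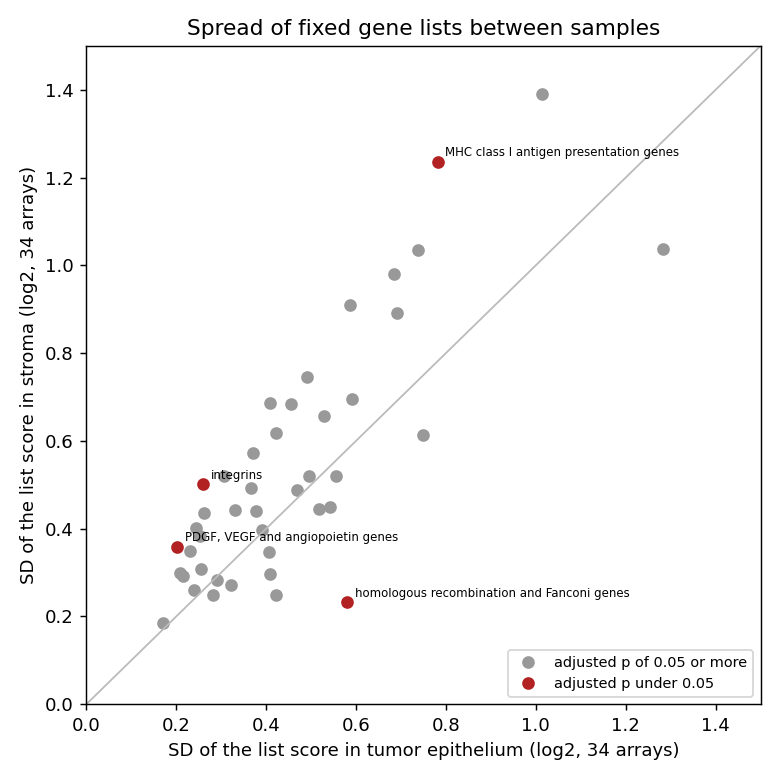
Each dot is a fixed gene list, with the SD of its score over 34 tumor epithelium samples on the horizontal axis and over the paired 34 stroma samples on the vertical axis, in log2 units; the line marks equal spread. The 4 red lists had adjusted p under 0.05, and homologous recombination and Fanconi genes are the red list under the line.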

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

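The alternatives for spread, coordination and marker scores, and the probe set choices, SD filter, tests without pairing and leaving out of pairs, were chosen after the values were seen. Planned level comparisons and their alternatives were not run, since centring makes them void. The cause of the changes below was not tested unless stated.

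Removing the first principal component changed most. The genes with r over 0.5 between compartments went from 261 to 401, with 171 in both sets, and lists that varied together from 4 to 1. Coordinated stroma lists went from 13 to 37, lists with larger spread in tumor epithelium from 1 to 2, and lists positively and negatively correlated with the epithelial score from 34 and 2 to 9 and 6. The log2 SD ratio turned to -0.37 for PDGF, VEGF and angiopoietin genes, -0.038 for MHC class I genes and -0.42 for integrins. Of the 34 lists positively correlated with the epithelial score, 16 turned negative: fibroblast (-0.371), smooth muscle (-0.165), pericyte (-0.0745) and macrophage markers (-0.0447), collagens (-0.400), basement membrane (-0.240), matrix glycoproteins (-0.527), cross-linking enzymes (-0.116), matrix proteases (-0.1155), TGF-beta (-0.484), BMP (-0.229), WNT (-0.121) and PDGF and VEGF genes (-0.381), mesenchymal factors (-0.680), immediate early genes (-0.0704) and integrins (-0.257).

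Centring each array on its median left 1 list, not 2, negatively correlated with the epithelial score. The mean over all probe sets of a gene left 0 lists with larger spread in stroma and gave 20 coordinated lists. With probe sets free of cross-hybridising suffixes preferred, red blood cell genes had r = -0.527 with the epithelial score. Restricting to 5642 genes with SD above the median in both compartments left 130 with r over 0.5, a smaller set by construction, and Spearman's rho gave 132.

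The spread tests were paired. With no replicate block on the same 68 arrays, 6 lists had larger spread in stroma in place of 3; on all 96 arrays it was 12, and the genes with larger spread in stroma were 444 in place of 698. The shared numbers are not shown to mark patients: deviations over all genes had a correlation over 0.1 in 22 of 34 pairs, not in all. On 200 genes chosen each time without the pair in question, 16 of 34 stroma samples had their own partner as the closest tumor sample, where 1 is expected by chance, a hint from the data and not the design. Leaving out each pair gave 0 to 6 lists that varied together, 188 to 315 genes with r over 0.5, and 558 to 881 and 1543 to 1791 genes with larger spread in stroma and tumor epithelium. Regressing out the 3-prime to 5-prime ratio kept the side of adjusted p = 0.05 for the 43 list correlations between compartments, and the direction of those that passed. In that setting 8 of 45 correlations with the epithelial score no longer passed. No alternative gave a ligand-receptor pair past adjusted p under 0.05. Signal over background cannot be read from centred values.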

Other observations

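The tests of the first axis, of the axis behind the correlations between compartments and of the within-pair swaps were chosen after those results had been seen; the tests of carried-over RNA and of cilium and germ-cell genes were set before theirs, although the themes came from inspecting the top genes.

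Genes of the motile cilium, a structure of some cells of the fallopian tube epithelium, varied more in tumor epithelium than in stroma. A list of 70 such genes, written after genes of this kind had appeared among those with the largest tumor spread, and leaving out those already seen, had 55 measured in both compartments. Their median log2 SD ratio of stroma over tumor epithelium was -0.56, against -0.17 for random lists matched on spread, at percentile 0.04, and 17 of them had at least a 2-fold larger SD in tumor epithelium. Between compartments their median r was 0.158 against 0.109 for random lists, at percentile 96.3, with 1 member over 0.5. Members of a shared program are not independent, as random genes are, so these percentiles overstate the certainty. A differentiated ciliated state that differs between tumors is a candidate explanation, and was not tested.

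Germ-cell genes such as GCNA and PRAMEF12 stood among the highest correlations between compartments, with r = 0.140 and 0.0642 without the 2 farthest pairs, but the class as a whole was not settled. Of 19 further germ-cell and cancer-testis genes 8 were measured, with a median r of 0.206 against 0.105 for random lists, at percentile 93.1, short of the level set in advance, with 1 member over 0.5.

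On the dominant axis of the stroma samples, matrix genes, reference genes and 18S ribosomal RNA (r = -0.704) shared a side. The bacterial control TrpnX-M lay on the opposite side (r = 0.801). The sign of the axis was set by choice. A lower share of stromal cells alone is argued against by the reference gene score, r = -0.971 with the axis, since those genes are used by all cells. The axis was computed from the same values, so the size of that r cannot be tested. Members of the reference list had a mean correlation of 0.783, but random lists matched on spread also reached 0.405. Hybridisation or scanning efficiency stays open, because the bioB spike-in had r = 0.0894 but the cre spike-in r = -0.343 (rho = -0.161). Loss of the 5-prime end of the RNA cannot be told apart, because the ACTB and GAPDH signals themselves follow the axis, on the side of the reference genes. Their 3-prime over 5-prime ratio had r = -0.386. RNA amount or amplification yield stays open, and no biological explanation was tested, as the labels give no group within stroma.

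The first axes of the compartments are argued against as the whole cause of the excess of genes that varied together, since 401 genes exceeded 0.5 with these axes removed, above the highest permuted count of 97. Of the 261 genes 171 were among the 401, and for the others the first axes stay open. Across the pairs these axes had r = 0.102, so little of them was shared to begin with. A technical factor shared by a pair on a later axis was not removed, so it stays open for all these genes. Tumor RNA carried over into stroma predicts a steeper relation in stroma samples with more epithelial marker RNA. The median interaction t over 260 of these genes was 0.127, at percentile 77 of permuted scores, and 0.633 at percentile 99 with the axis removed. The settings disagree, so carried-over RNA cannot be told apart from variation shared by a pair, and stromal RNA in tumor epithelium was not tested for these genes.

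Interferon-stimulated genes kept their correlation between compartments with the first axes removed, r = 0.554, which argues against those axes as the whole cause. A technical factor shared by a pair on a later axis was not tested. Stromal RNA carried over into tumor epithelium stays open, since r was 0.476 with the fibroblast score regressed out there, but the interferon score hardly followed that score (r = 0.111, p = 0.526), so the regression had little to remove. In stroma the interferon score had r = 0.346 with the epithelial score across the 34 pairs, so regressing that score out had limited variation to remove. With it regressed out r was 0.539, but the interaction with the epithelial score lay at percentile 59.8 of permuted scores, above the bound set in advance. Tumor RNA in stroma therefore stays open. An interferon response shared by both compartments of a pair may also account for it, and no label bears on that.

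More genes had larger spread, in both directions, than random swaps of the compartments within pairs gave. Such swaps treat the values of both compartments as exchangeable. The probe set median was 0 for 100% of probe sets in stroma and for 33.2% in tumor epithelium, so their processing may differ. A difference in processing or array quality between compartments would also exceed the swaps, and stays open. Of 100 splits that swapped compartments within pairs, the real one included, 1 gave as many as the 698 genes of the stroma side and 1 as many as the 1691 genes of the tumor side, that is the real one each time, and the highest of the others, in either direction, was 405. The others called a median of 118 genes on their larger side, so part of the calls on each side may be false.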
